A study of Mus musculus with 2 samples.

How the data were processed

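Bladder mucosa of female wild-type mice was compared between 1 library made 1 day after PBS and 1 library made 1 day after infection with UTI89. Per the labels' protocols, total RNA was isolated with a column kit from micro-dissected urothelium, mRNA was enriched, and double-stranded cDNA was end-repaired, ligated to adaptors, size-selected and amplified. Per the submitters' processing notes, CASAVA 1.8, TopHat2 and HTSeq were used, with neither their roles nor their order stated. The genome build, the annotation, the strand setting of the counting and the tool of the authors' comparison were not given in the sources used here, so no coordinates are printed. Values of overlapping or antisense genes and of near-identical copies are uncertain for that reason.

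The data were 1 table of 22196 genes with a value per library, a log2 fold change, a p-value, a q-value and a mark of significance. Per the file headers the 2 value columns are read counts, but the deposited values are CPM: each column holds whole multiples of 1 step (0.0394 in the PBS library and 0.0382 in the infected library), and the columns sum to 1009435 and 988657. The steps correspond to scaled library sizes of 25381271 and 26174177 reads, and 100% of the values above 0 were whole multiples within 0.02 reads. No value lay between 0 and 1 CPM, so a gene listed at 0 can have had up to about 25 reads. The authors' deposited log2 fold change equalled the log2 ratio of the 2 values within 5.0e-05 for all 12678 genes with both values above 0. It was also given for genes listed at 0, so it rests on values that the table does not list. The p-value and q-value in the authors' deposited table compare 1 library with 1 library, and the authors' mark went with q-values up to 0.0050 and an absolute log2 fold change of 1.00 or more. Values were missing for 4952 genes, which were left out; of the other 17244, 3797 were listed at 0 in both libraries and 13447 were compared. Gene symbols came from a GENCODE M21 table, which matched 21778 of 22196 identifiers (98.1%).

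The design fixed before the data were examined assumed raw counts; since the unit was CPM, its stated fallback for normalized values was used. The ratio of the infected over the PBS library was taken as log2(CPM + 1), with a pseudocount of 1 CPM, and a gene was called higher or lower beyond a log2 ratio of 1 or -1. This scale understates the change of low genes listed above 0 in both libraries. For a gene listed at 0 in 1 library it can understate or overstate the change. Xcr1, for example, had a log2 ratio of 1.05 on this scale and 0.18 in the authors' deposited table. No test across genes, p-value or count model was used, since 1 library per group leaves no estimate of the spread between animals. Printed folds are ratios of CPM without the pseudocount, and no fold is given where a library is listed at 0. Their intervals are exact (Clopper-Pearson) 95% binomial intervals from the reads behind each value, chosen after seeing the data; they cover counting error only, and amplified reads are not independent molecules. For 760 genes listed at 0 in 1 library, the reads for the interval rule were restored from the authors' deposited fold change (99.2% came out whole within 0.1 reads and 100% lay under the floor). For another 9 genes without such a fold change, the interval rule took the most reads the floor allows.

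In total 47 gene lists were fixed before the data were examined. For each of the 45 lists with 3 or more measured members, the median log2 ratio was given with its percentile among 10000 random lists matched on mean expression in 20 bins, as a description of these libraries. A list was said to be within the range of random lists where its median lay in their central 95%. The named genes were the 12 with the highest and the 12 with the lowest ratio at a mean of 20 CPM or more (predicted gene models left out), from each list the 4 members with the largest absolute ratio and the most abundant member, all PRC2 genes with Kdm6a and Kdm6b, and the 5 most abundant genes per library. Some genes that this rule takes are not reported here. A subset of the list members is printed, and genes outside the rule are said to be so. Members named only to complete a short count (Gata3, Krt1, Cd44, Igfbp2, Vegfa, Egf, Pthlh, Gsto1, Aldh1a2, Dhrs9, Fn1, F3, Kit, Hdc and Rps2) were chosen after their values were seen. No replicate could be left out, and no library batch is given in the labels.

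The calculation was tested on simulated reads for 12994 genes with the depths of both libraries. The simulated reads held counting error only, and the changed genes were drawn from those with a mean of 5 CPM or more. All 50 genes set 3-fold higher, 50 set 6-fold higher, 50 set 3-fold lower and 50 set 6-fold lower passed the size rule (100%). At that level such changes pass almost by construction, so the result does not cover lower genes. The counting intervals held the true fold for 96.0%, 94.0%, 98.0% and 96.0% of them. Of 12794 genes left equal, 114 (0.891%) passed by counting error together with the floor. Each simulated level was the mean of the 2 listed values, with a zero taken as 0. Genes listed at 0 in both libraries were left out. This share therefore does not measure wrong calls among genes listed at 0 in 1 library. The alternatives were total-count, median-of-ratios and upper-quartile scaling, no filter or a filter of 50 reads, pseudocounts of 0.1 and 5 CPM, a 4-fold limit, members of several lists left out, and other thresholds in the authors' table. Added after seeing the data were restored values under the floor, zeros set to the floor, the counting interval as the limit, and the mark in the authors' table. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.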

Results

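RNA was measured in the bladder mucosa of female wild-type mice 1 day after inoculation with phosphate-buffered saline (PBS) or infection with UTI89, a strain of uropathogenic Escherichia coli isolated from cystitis and widely used in mouse models of urinary tract infection. Each group held 1 library, so no difference has a replicate check, and whether a library came from 1 mouse or from several was not given in the sources used here. The values listed for the PBS library stood for 25620733 reads and those for the infected library for 25877279 reads. At this depth 1 CPM, a read count scaled to a common library size, equalled about 25 reads in the PBS library and 26 reads in the infected library, and values under 1 CPM were listed as 0. After this floor, 13009 genes were listed above 0 in the PBS library and 13116 in the infected library. The 5 genes with the largest shares in the PBS library were Eef1a1, Gstm1, mt-Co1, Eef2 and Upk1a, together 4.03% of the listed total. In the infected library they were Eef1a1, mt-Co1, Krt5, Krt15 and mt-Co2, together 2.78%. Folds are ratios of CPM with an exact 95% counting interval in square brackets, which covers counting error only and not the difference between animals.

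The comparison asked which transcripts differed between infected and PBS-treated mucosa on day 1; the title of the study names Polycomb repressive complex 2 (PRC2), a histone H3 lysine 27 methyltransferase, and inflammation. More than 2-fold higher in the infected library were all 40 measured cell cycle genes and 16 of 21 antimicrobial and acute-phase genes. So were 12 of 15 inflammatory cytokines and receptors, all 12 CC chemokines and 14 of 15 neutrophil genes. Outside the cell cycle genes, part of these passed by a zero in the PBS library. Of the 12 CC chemokines, 9 had a counting interval wholly above 2-fold. More than 2-fold lower were 5 of 13 genes of superficial urothelial cells, 9 of 15 smooth muscle and pericyte genes and 8 of 20 xenobiotic and retinoid enzymes. Among 13447 genes listed above 0 in at least 1 library, 1266 (9.41%) were more than 2-fold higher in the infected library and 796 (5.92%) more than 2-fold lower, on a scale of log2(CPM + 1). Counts of genes past 2-fold use this scale throughout, while printed folds are plain ratios of CPM, so a gene with a fold slightly above 2, or a low gene, can be left out of a count. Of the genes counted, 438 of the higher and 331 of the lower genes were listed at 0 in the other library and pass the 2-fold limit by construction, since the floor and the added constant are both 1 CPM. With the counting interval required to lie wholly beyond 2-fold, 921 genes were higher and 444 lower.

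**Figure D1:**
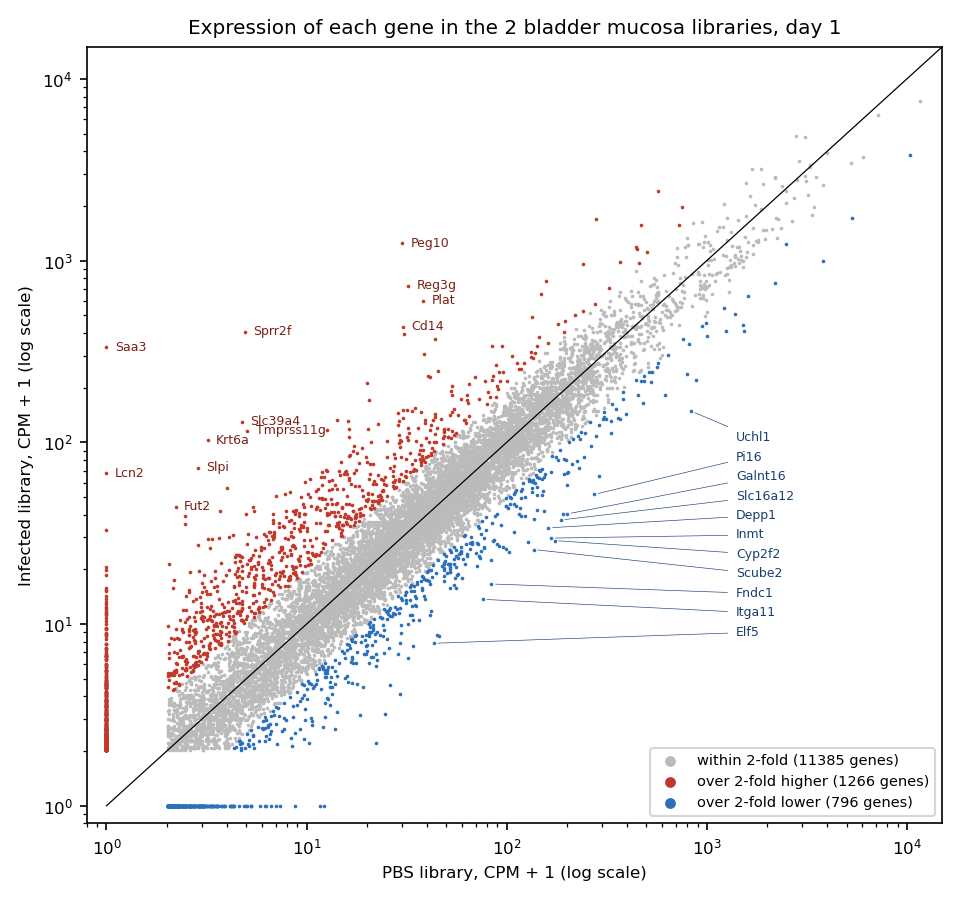
CPM + 1 of each of 13447 genes in the PBS library (x axis, log scale) and in the infected library (y axis, log scale), with the line of equal values. Red points are the 1266 genes more than 2-fold higher and blue points the 796 more than 2-fold lower in the infected library; genes listed at 0 in a library lie at 1 on its axis, and the 12 genes with the highest and 11 of the 12 with the lowest ratios at a mean of 20 CPM or more are named.

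Saa3, an acute-phase protein, was listed at 0 (under 1 CPM) in the PBS library and at 332 CPM in the infected library, with a log2 fold change of 8.87 in the authors' deposited table. Sprr2f, a cornified envelope precursor of a family of near-identical genes, stood at 3.90 CPM in the PBS library and 406 CPM in the infected library, a 104-fold difference [85.4, 128]. Lcn2, which binds bacterial siderophores, was listed at 0 in the PBS library and at 66.4 CPM in the infected library. The imprinted, retrotransposon-derived gene Peg10 was 42.8-fold higher [39.8, 46.1], at 1246 CPM against 29.1 CPM. The stress keratin gene Krt6a was 46.0-fold higher [35.3, 61.1] and the zinc importer gene Slc39a4 34.4-fold higher [28.1, 42.6]. Slpi, a secreted protease inhibitor, was 38.7-fold higher [29.0, 52.9], and the serine protease gene Tmprss11g 28.3-fold higher [23.2, 34.7]. Reg3g, an antibacterial C-type lectin, stood at 726 CPM against 31.2 CPM, a 23.3-fold difference [21.7, 25]. The fucosyltransferase gene Fut2 was 35.3-fold higher [24.8, 52.3]. Plat, tissue plasminogen activator, was 16.2-fold higher [15.1, 17.3], and Cd14, a co-receptor for bacterial lipopolysaccharide, 14.8-fold higher [13.7, 15.9].

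At the other end, the 12 genes with the lowest ratios were 4.90- to 6.21-fold lower in the infected library. Cyp2f2, a cytochrome P450, was 6.21-fold lower [5.74, 6.72] and Elf5, an ETS transcription factor, 6.18-fold lower [5.27, 7.28]. The collagen-binding integrin gene Itga11 was 5.92-fold lower [5.27, 6.68]. Inmt, a methyltransferase, was 5.77-fold lower [5.34, 6.25]. The ubiquitin hydrolase gene Uchl1 stood at 835 CPM in the PBS library and 148 CPM in the infected library, 5.66-fold lower [5.47, 5.86]. Scube2, Pi16, a marker of adventitial fibroblasts, and Fndc1 were 5.47-, 5.38- and 5.31-fold lower. Slc16a12, Galnt16 and Depp1 were 5.10-, 5.07- and 4.90-fold lower.

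Antimicrobial and acute-phase genes were higher as a group: 16 of 21 measured members were more than 2-fold higher and 1 more than 2-fold lower. Of the 16, 7 were listed at 0 in the PBS library, and 14 were also past the counting interval. The list had a median log2 ratio of 1.86, above all 10000 random lists of the same size and expression. Lyz2, lysozyme of macrophages and other myeloid cells, was 2.67-fold higher [2.55, 2.80], and Wfdc2, at 858 CPM in the PBS library, was 1.87-fold higher [1.84, 1.91]. The member that was lower, Defb1, a beta-defensin named after its value was seen, was 5.05-fold lower [4.28, 5.99]. Of 15 measured inflammatory cytokines and receptors, 12 were more than 2-fold higher, 9 of them listed at 0 in the PBS library, and the list median was 2.17. Il33, an alarmin of epithelial and stromal cells, was 13.3-fold higher [12.4, 14.4], and Il1rn, the interleukin-1 receptor antagonist, 9.92-fold higher [8.87, 11.1]. Il1b was listed at 0 in the PBS library and at 31.9 CPM in the infected library, and Il17a at 0 and 5.73 CPM. All 12 measured CC chemokines were more than 2-fold higher on the scale with the added constant, 7 of them listed at 0 in the PBS library. Of the 12, 9 were also past the counting interval. Among those listed at 0, Ccl12 and Ccl24 had log2 fold changes of 0.67 and 0.71 in the authors' deposited table, under 2-fold. Ccl20 had none there. Ccl8 was 5.82-fold higher [5.03, 6.76] and Ccl22 14-fold higher [9.64, 21.0], while Ccl7 was listed at 0 and 14.3 CPM. Among 11 measured CXC chemokines 6 were more than 2-fold higher, 5 of them listed at 0 in the PBS library. The neutrophil chemoattractant Cxcl1 was listed at 0 in the PBS library and at 18.8 CPM in the infected library, and Cxcl5 at 0 and 8.48 CPM, whereas Cxcl14, the most abundant member, was 1.15-fold lower [1.11, 1.19]. The medians of the CC and CXC chemokines were 2.02 and 1.67, both above all 10000 random lists. With zeros set to the floor of 1 CPM, the medians were 1.17 for the cytokines, 1.71 for the CC and 0.67 for the CXC chemokines.

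Of 22 measured NF-kB feedback genes and targets, 14 were more than 2-fold higher and 1 more than 2-fold lower, with a median of 1.13. The RNase gene Zc3h12a, which degrades cytokine mRNAs, was 11.1-fold higher [10.1, 12.2]. The NF-kB cofactor genes Bcl3 and Nfkbiz were 8.56-fold [7.70, 9.53] and 6.88-fold [6.19, 7.67] higher, and P-selectin (Selp) 8.28-fold higher [7.0, 9.85]. E-selectin (Sele), named after its value was seen, was the lower member, at 2.54-fold [2.28, 2.82]. Pattern-recognition and inflammasome genes had a median of 0.88, with 9 of 22 more than 2-fold higher, 3 of them listed at 0 in the PBS library, and none lower; Nlrp3 and Clec4e were listed at 0 in the PBS library and at 4.97 and 5.96 CPM in the infected library. Type I interferon response genes had a median of 1.19, with 14 of 25 more than 2-fold higher, 1 of them listed at 0 in the PBS library, and none lower. Isg15 was 5.23-fold higher [4.20, 6.58] and Oasl1 7.30-fold higher [5.19, 10.5]. MHC class II genes had a median of 0.85, with 3 of 8 more than 2-fold higher, among them Ctss, a lysosomal protease, at 3.51-fold [3.23, 3.82], with H2-DMb1 and Ciita at 2.14-fold [1.84, 2.5] and 2.34-fold [1.89, 2.92]; Cd74 was 1.40-fold higher [1.36, 1.44]. H2-DMa was 2.08-fold higher [1.81, 2.40] as a ratio of CPM but fell short on the scale with the added constant.

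Neutrophil and monocyte genes were higher alongside these. Of 15 measured neutrophil genes, 14 were more than 2-fold higher, 12 of them listed at 0 in the PBS library, and the median was 2.73. With the zeros set to the floor of 1 CPM the median was 1.82. Cd177, S100a9, Ltf and Csf3r were each listed at 0 in the PBS library and at 14.4, 11.3, 10.6 and 10.3 CPM in the infected library, and Itgam, an integrin of myeloid cells, was 4.21-fold higher [3.56, 5.00]. Monocyte and macrophage genes had a median of 1.15, with 11 of 19 more than 2-fold higher, 4 of them listed at 0 in the PBS library. Ccr2, the chemokine receptor of inflammatory monocytes, was 9.17-fold higher [7.54, 11.2]. Dendritic cell genes had a median of 1.05 over 7 members, at the 97.0th percentile and within the range of random lists. T and NK cell genes had 0.73 over 10 members, at the 97.9th percentile and above that range, with 2 of the 10 more than 2-fold higher and 1 lower, all 3 by a zero in 1 library. Lck and, named after their values were seen, Cd3d, Cd3e, Cd3g and Il7r were 2.19-, 2.39-, 2.26-, 2.00- and 2.21-fold higher as ratios of CPM but are not counted on the scale with the added constant. The measured members of both lists were under 14 CPM. With zeros set to the floor the dendritic cell median was 0.44. Without the filter on low genes it was 0.42, above the range of random lists, and the T and NK cell median was 0. In these lists Itgax and Ccr7 were 2.89-fold [2.35, 3.58] and 4.16-fold [2.80, 6.37] higher, Xcr1, Batf3, Cd2 and Gzmb were listed at 0 in the PBS library only, and Gzma at 0 in the infected library only. The B and plasma cell list had 3 measured members and a median of 0.37, within the range of random lists. That median was the value of Sdc1, at 1126 CPM in the PBS library and 1453 CPM in the infected library. In the same order, Xbp1 stood at 156 and 251 CPM, and Jchain was listed at 2.92 CPM and at 0. Whether Sdc1 and Xbp1 reflect B and plasma cells in this tissue was not tested. Of 14 mast cell and eosinophil genes, Kit (2.88 and 2.33 CPM) and Hdc (0 and 5.31 CPM) were the 2 measured. Red blood cell and platelet genes had a median of -0.23, within the range of random lists.

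**Figure D2:**
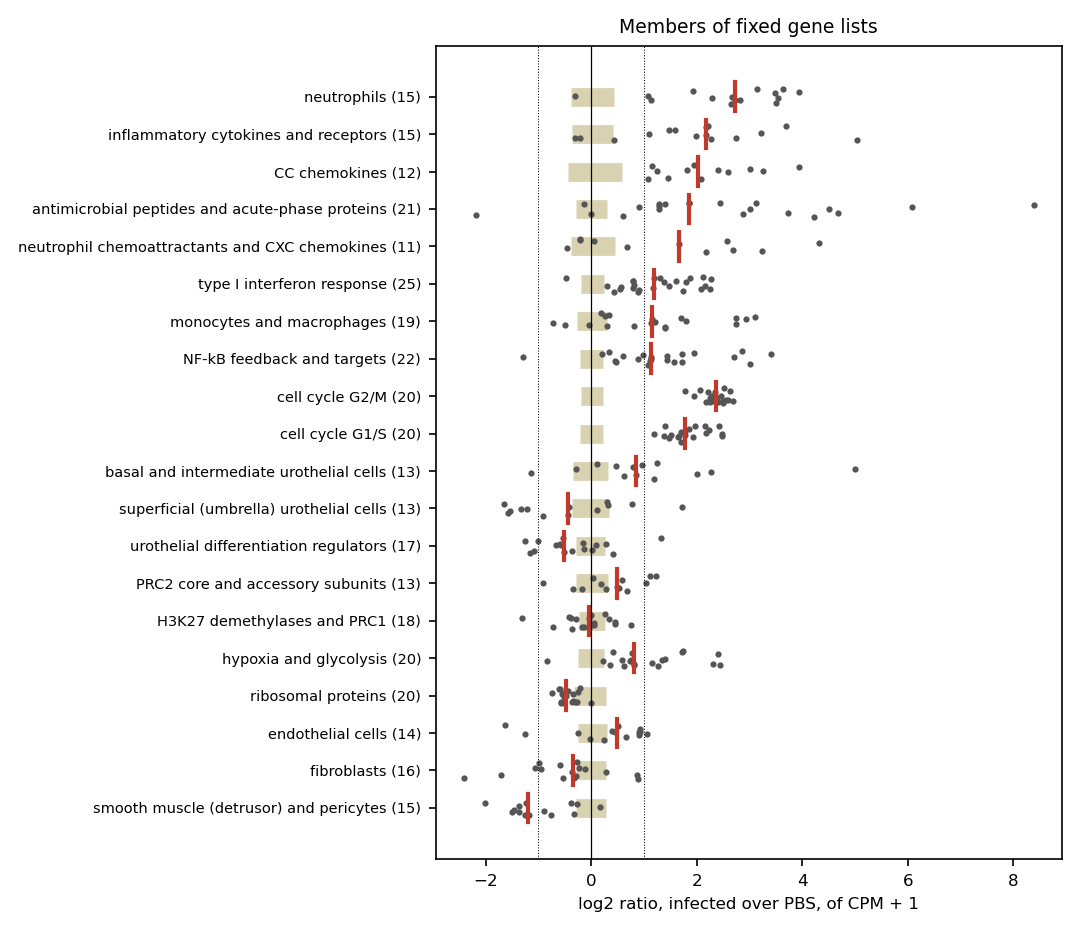
Log2 ratio of CPM + 1, infected over PBS, of each measured member (grey points) of 20 gene lists fixed before the data were examined, with the number of measured members in parentheses. Red lines are list medians, beige bars hold the central 95% of medians of 10000 random lists matched on expression, and dotted lines mark 2-fold; the neutrophil list has its median at 2.73 and the smooth muscle list at -1.20.

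Genes of the urothelium, the stratified epithelium that lines the bladder, differed in both directions, in a library where neutrophil genes were higher (median 2.73) and smooth muscle genes lower (median -1.20). Of 13 measured genes of superficial (umbrella) cells, 5 were more than 2-fold lower and 1 more than 2-fold higher, with a median of -0.44 at the 0.695th percentile of random lists. Upk1a, a uroplakin of the apical plaques, stood at 5351 CPM in the PBS library and 1715 CPM in the infected library, 3.12-fold lower [3.09, 3.15]. Upk3a was 2.92-fold lower [2.87, 2.97] and Krt20, the keratin of the most differentiated cells, 2.98-fold lower [2.86, 3.11]. Upk2 and Upk3b, named after their values were seen, were 2.5-fold [2.46, 2.55] and 2.33-fold [2.28, 2.39] lower. Upk1b and Upk3bl, also named after their values were seen, did not pass 2-fold, at 1.87-fold [1.85, 1.89] and 1.44-fold [1.13, 1.84] lower. The protease gene Prss27 was the higher member, at 3.39-fold [3.10, 3.71]. Among 13 genes of basal and intermediate cells 5 were more than 2-fold higher and 1 more than 2-fold lower, with a median of 0.84, above all random lists. Krt5 was 1.74-fold higher [1.73, 1.76] at 4864 CPM in the infected library and Krt15 1.54-fold higher [1.53, 1.56]. Krt14 was 5.11-fold higher [4.55, 5.75] and Col17a1, a hemidesmosome collagen, 4.04-fold higher [3.85, 4.24]. Itga6 and Cd44 were 2.38- and 2.30-fold higher, and Krt6a is given above; Igfbp2 was the lower member, at 2.19-fold [2.15, 2.24].

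**Figure D3:**
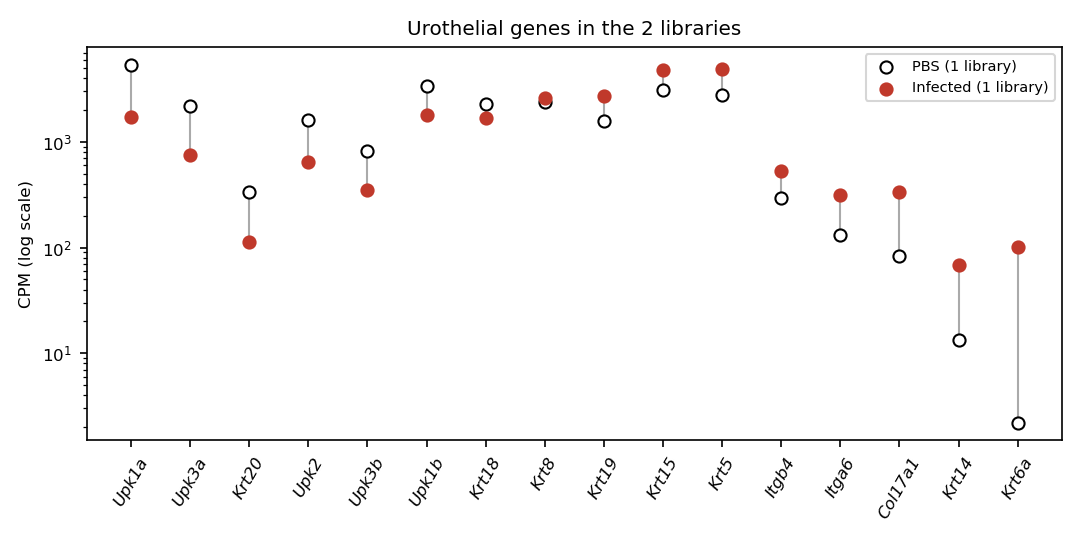
CPM on a log axis of 16 urothelial genes, chosen after their values were seen, in the PBS library (open points) and the infected library (red points), 1 library each. Upk1a, Upk3a and Krt20 are lower in the infected library, and Krt5, Col17a1, Krt14 and Krt6a are higher.

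Regulators of urothelial differentiation had a median of -0.52, below all 10000 random lists, with 4 of 17 more than 2-fold lower and 1 higher. Grhl3 and Klf4, transcription factors of epithelial barrier formation, were 2.25-fold [2.16, 2.34] and 2.41-fold [2.27, 2.55] lower, Bmp2 2.13-fold lower [2.00, 2.26] and Gata3 2.02-fold lower [1.95, 2.08]. Elf3 was 2.5-fold higher [2.41, 2.58]. Squamous and stress keratin and envelope genes had a median of 1.13, with 9 of 16 more than 2-fold higher, 5 of them listed at 0 in the PBS library, and 1 lower. Krt1, at 3.70 and 1.03 CPM, was the lower one, and the median was 0.63 with zeros set to the floor and 0 without the filter on low genes. Within the Sprr2 family, whose copies are so alike that reads could be divided between them, Sprr2e and Sprr2h were listed at 0 in the PBS library and at 10.5 and 11.9 CPM in the infected library. Sprr1a, the most abundant member, was 1.02-fold higher [1.01, 1.03]. Junction genes had a median of 0.37, with Cldn7 and Epcam 2.26-fold [2.17, 2.35] and 2.16-fold [2.07, 2.25] higher and Cldn8 4.83-fold lower [4.51, 5.17]. Cldn5, also in the endothelial list, was the other member more than 2-fold lower, at 2.51-fold [2.17, 2.91]. Of 14 urothelial channels and transporters 2 were more than 2-fold higher and 2 lower; the sodium channel subunit genes Scnn1b and Scnn1g were 2.35-fold [2.09, 2.64] and 2.61-fold [2.38, 2.86] lower, and P2ry2 and Atp1b1 2.04-fold [1.91, 2.17] and 2.29-fold [2.14, 2.46] higher.

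PRC2 genes had a median log2 ratio of 0.49 over 13 measured members, at the 99.7th percentile of random lists. In the same library the cell cycle genes were higher, with medians of 1.77 (G1/S) and 2.36 (G2/M). Of the PRC2 genes, 3 were more than 2-fold higher and none more than 2-fold lower. Of these 3, Ezh2, Phf19 and Epop, only Epop was also past the counting interval. None of the 3 carried the mark in the authors' deposited table, and none passed 2-fold with an added constant of 5 CPM. The mark was sparse in some inflammatory lists too, with 2 of 15 neutrophil, 4 of 15 cytokine and 2 of 25 interferon genes marked higher. It covered 11 of 22 NF-kB genes, 16 of 20 G1/S genes and 19 of 20 G2/M genes. Ezh2 (ENSMUSG00000029687), the catalytic subunit of proliferating cells, stood at 22.4 CPM in the PBS library and 47.3 CPM in the infected library, 2.11-fold higher [1.91, 2.34]. In the authors' deposited table Ezh2 had a log2 fold change of 1.08 and a q-value of 0.022 and was not marked as significant. The accessory subunit genes Phf19 and Epop were 2.39-fold [1.94, 2.95] and 3.10-fold [2.21, 4.41] higher, both at low levels of 12.2 and 5.62 CPM in the infected library. The core genes Eed, Suz12, Rbbp7 and Rbbp4 were 1.52-, 1.41-, 1.61- and 1.22-fold higher, Aebp2 1.44-fold higher and Mtf2 1.14-fold higher [1.01, 1.30]. Ezh1, the alternative catalytic subunit, was 1.27-fold lower [1.18, 1.36], Phf1 1.95-fold lower [1.73, 2.19] and Jarid2 1.13-fold lower [1.02, 1.24]. Lcor, at 13.2 and 13.6 CPM, did not differ beyond counting error. The H3K27 demethylase genes Kdm6a (37.9 and 37.1 CPM) and Kdm6b (106.7 and 106.6 CPM) did not differ beyond counting error either. Together with PRC1 genes the demethylases had a median of -0.04 over 18 members, with Cbx7 2.56-fold lower [2.28, 2.88]. A list of 20 measured homeobox and other developmental genes often under PRC2 had a median of -0.19, within the range of random lists, but of -0.0538 and below that range without the filter on low genes. None of them was more than 2-fold higher and 2 were lower on the scale with the added constant. Bmp4 was 2.19-fold lower [2.02, 2.38]. Irx3, listed at 1.22 CPM in the PBS library and at 0 in the infected library, passed only by that zero. Its log2 fold change in the authors' deposited table was -0.35.

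All 40 measured cell cycle genes were more than 2-fold higher in the infected library, each with its counting interval wholly above 2-fold. The median was 1.77 for 20 G1/S genes and 2.36 for 20 G2/M genes, both above all random lists. Mki67, a marker of cycling cells, stood at 39.6 CPM in the PBS library and 230 CPM in the infected library, 5.80-fold higher [5.43, 6.21]. Ccnb1 was 7.19-fold higher [6.16, 8.43], Cdk1 6.81-fold higher [5.92, 7.88] and Rrm2 5.83-fold higher [5.25, 6.48]. Uhrf1, a maintenance factor of DNA methylation, was 5.80-fold higher [5.29, 6.35]. Of 12 replication-dependent histone genes 4 were measured, with a median of 0.37, within the range of random lists. Hist1h4i, at 0 and 1.60 CPM, and Hist2h2aa1, at 2.64 and 1.60 CPM, lay near the floor. How well the mRNA enrichment captured histone transcripts was not tested. Growth factor and repair genes had a median of -0.07, with 5 of 23 more than 2-fold higher and 4 lower. The EGF receptor ligand genes Areg, Ereg and Hbegf were 6.56-fold [5.72, 7.55], 9.86-fold [7.32, 13.6] and 5.04-fold [4.45, 5.71] higher, and Tgfb1 and Vegfa 2.59-fold [2.45, 2.75] and 2.25-fold [2.10, 2.41] higher. Wnt5a was 2.19-fold lower [2.12, 2.27] and Bmp4 is given above, and Egf and Pthlh, at 1.1 and 1.02 CPM in the PBS library, were listed at 0 in the infected library.

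Hypoxia and glycolysis genes had a median of 0.82, with 9 of 20 more than 2-fold higher and none lower. Hif1a, the oxygen-regulated transcription factor, was 4.98-fold higher [4.81, 5.15], Hk2 5.55-fold higher [5.21, 5.92], the lactate exporter gene Slc16a3 5.53-fold higher [4.97, 6.15] and Ldha 3.35-fold higher [3.28, 3.41]. Oxidative stress, iron and heme genes had a median of 1.03, with 10 of 19 more than 2-fold higher, among them Txnrd1 at 4.44-fold [4.29, 4.60] and Steap4 at 9.0-fold [7.18, 11.4]. Xenobiotic and retinoid enzymes had a median of -0.29 at the 1.57th percentile, with 8 of 20 more than 2-fold lower and 5 higher. Gstm1, a glutathione transferase of a gene family with close copies, stood at 10376 CPM in the PBS library and 3832 CPM in the infected library, 2.71-fold lower [2.69, 2.73], and Adh7 was 3.76-fold lower [3.51, 4.03]. Aldh1a3, which makes retinoic acid, was 26.3-fold higher [19.0, 37.6], and Gpx2, Gsto1 and Aldh1a2 were 4.62-fold [4.26, 5.02], 2.62-fold [2.58, 2.66] and 2.52-fold [2.34, 2.73] higher, with Dhrs9 listed at 0 and 1.15 CPM. Nuclear-encoded oxidative phosphorylation genes had a median of 0.32 and lipid and sterol genes -0.29, at the 99.6th and 1.15th percentile, and none of either passed 2-fold on the scale with the added constant. Ndufa4, of the first list, was 2.01-fold higher [1.92, 2.10] as a ratio of CPM and carried the mark in the authors' deposited table. The 13 mitochondrially encoded genes had a median of -0.04, within the range of random lists. The 20 ribosomal protein genes had a median of -0.48 at the 0.06th percentile, and none passed 2-fold. All 20 had lower values in the infected library, although Rps2, at 1011 and 1008 CPM, did not differ beyond counting error and was higher under total-count scaling; Rps6 was 1.68-fold lower [1.66, 1.70]. Reference genes used for normalisation had a median of 0.29, and within that list Pgk1 was 2.44-fold higher [2.28, 2.61] and Eef1a1 1.54-fold lower [1.53, 1.55].

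Genes of matrix remodelling had a median of 0.85, with 9 of 19 more than 2-fold higher, 5 of them listed at 0 in the PBS library, and 1 lower. Timp1 was 9.93-fold higher [8.81, 11.2] and Adamts4 15.3-fold higher [12, 19.8], and Mmp3 and Mmp10 were listed at 0 in the PBS library and at 9.86 and 9.44 CPM in the infected library. The lower member was Fn1, fibronectin, at 2.01-fold [1.94, 2.08]. Complement and coagulation genes had a median of 0.11 and prostaglandin genes 0.13, both within the range of random lists. In the first, 5 of 18 were more than 2-fold higher, among them Plaur at 4.17-fold [3.75, 4.65], C5ar1 at 3.06-fold [2.41, 3.92] and F3 at 2.22-fold [1.92, 2.56], with F10 listed at 0 and 7.56 CPM. In the second, 2 of 12 were more than 2-fold higher and 2 lower: Ptgs2, the inducible cyclooxygenase, at 19.3-fold higher [13.1, 29.5] and Alox5ap at 3.09-fold higher [2.55, 3.77], and Hpgd, which degrades prostaglandins, at 2.40-fold lower [2.18, 2.63] and Alox12 at 2.13-fold lower [1.90, 2.39]. Cell death genes had a median of 0.73, with 3 of 15 more than 2-fold higher: the necroptosis genes Ripk3 and Mlkl at 4.63-fold [4.05, 5.30] and 3.79-fold [3.44, 4.19], and Fas at 2.71-fold [2.18, 3.38]. Immediate-early genes, which also respond to dissection, had a median of 0.88, with 7 of 17 more than 2-fold higher, 2 of them listed at 0 in the PBS library. Egr1 was 6.09-fold higher [5.54, 6.71] and Jun 2.25-fold higher [2.11, 2.41].

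Markers of other cell layers differed between the libraries as well. Of 15 smooth muscle and pericyte genes, 9 were more than 2-fold lower and none higher, with a median of -1.20, below all random lists. The pericyte marker Rgs5 was 4.03-fold lower [3.91, 4.15], Myl9 2.85-fold lower [2.68, 3.03] and Myh11, smooth muscle myosin, 2.77-fold lower [2.65, 2.91]. Skeletal muscle genes, with 4 measured members all listed under 3 CPM, had a median of -1.47; Ckm, Myh7 and Acta1 were listed at 0 in the infected library. With values under the floor restored, this median was -0.50, within the range of random lists. Fibroblast genes had a median of -0.35 at the 0.97th percentile, with 3 of 16 more than 2-fold lower (Pi16, Mfap5 and Col6a2), and the most abundant, Col1a1, was 1.51-fold lower [1.5, 1.53]. Endothelial genes had a median of 0.49 at the 99.8th percentile, with 1 of 14 more than 2-fold higher, not past the counting interval, and 2 lower. Ackr1 was 2.28-fold higher [1.88, 2.78] and Flt1 1.92-fold higher [1.8, 2.05], while Lyve1 was listed at 2.09 CPM in the PBS library and at 0 in the infected library. Cldn5, given above, was 2.51-fold lower, and Vwf, the most abundant member, 1.19-fold lower [1.14, 1.24]. Nerve, glia and adipocyte genes had a median of -0.78 over 7 members, but -0.22 with zeros set to the floor, within the range of random lists. Uchl1, given above, was 5.66-fold lower, Fabp4 2.61-fold lower [2.55, 2.67], and Prph was listed at 1.22 CPM and at 0. Of 15 listed genes 7 were measured, with a sum of 1852 CPM in the PBS library. Fabp4 and Uchl1 made up most of that sum, at 999 and 835 CPM, while Ncam1 stood at 7.29 CPM. Whether Fabp4 and Uchl1 reflect nerve or fat cells in this tissue was not tested.

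The authors' deposited table gave 541 genes higher and 271 lower in the infected library at a q-value under 0.05 and an absolute log2 fold change of 1 or more. Its own mark of significance in the authors' deposited table covered 599 genes, 389 higher and 210 lower, of which 593 were more than 2-fold different in the same direction here. These q-values compare 2 libraries, not the conditions, and the counts of higher and lower genes moved by more than 1.5 times with the added constant: at 5 CPM they were 593 and 290.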

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

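No paired analysis was possible because each group has 1 library. The counting interval, restored values, zeros at the floor and the mark in the authors' table were chosen after seeing the data. The count of 1266 higher genes ran from 949 to 1373 across scalings, filters, floor treatments and a pseudocount of 0.1 CPM and was 921 by the counting interval, but was 593 with a pseudocount of 5 CPM and 319 at 4-fold. The count of 796 lower genes was 545 to 827 across scalings and filters and 899 with a pseudocount of 0.1 CPM. It was 290 with a pseudocount of 5 CPM, 522 with restored values, 490 with zeros at the floor, 444 by the counting interval and 58 at 4-fold. A larger pseudocount, a floor and a higher limit lower these counts by construction. With no fold threshold the authors' deposited table gave 1025 and 665 genes, against 541 and 271. The scalings moved the median of all genes by 0.028, -0.001 and -0.031.

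Over 45 list medians and 421 settings, 408 stayed on the same side of the central 95% of random lists, 9 moved into it, 4 moved out of it and 0 reversed. Without a filter the medians were -0.0538 for the homeobox list (out of it), 0 for squamous genes, 0.42 for dendritic cells (out of it), 0 for T and NK cells, 0 for skeletal muscle and 0.29 for reference genes (out of it). With 50 reads T and NK cells had 0.75 and nerve, glia and adipocytes -0.50; the latter had -0.32 with a pseudocount of 5 CPM, -0.50 with restored values and -0.22 with zeros at the floor. Restored values gave -0.50 for skeletal muscle, and a pseudocount of 5 CPM gave 0.29 for reference genes (out of it). Without a filter, genes listed at 0 in both libraries enter both the lists and the random lists; for the other settings the cause was not tested. Of 1871 settings over 234 named genes, 1586 stayed within the counting interval, 285 moved beyond it and 0 reversed. Depth limits the genes near 1 CPM most, where a value rests on about 25 reads. The planned scalings of raw counts were run on CPM, and priors of 0.5 and 5 counts were replaced by the pseudocounts.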

Other observations

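All tests in this part were chosen after the results they bear on were seen, and so were the genes named here outside the lists. Several genes that belong to none of the fixed lists were also much higher in the infected library. The serpin genes Serpina3n, Serpina3m, Serpina3g and Serpina3f, a cluster of close copies between which reads could be divided, were 4.25-fold [4.17, 4.33], 4.92-fold [4.48, 5.43], 5.20-fold [4.55, 5.95] and 5.26-fold [4.52, 6.15] higher. Socs3, a feedback inhibitor of cytokine signalling, was 8.75-fold higher [7.97, 9.62]. Akr1b8, an aldo-keto reductase, stood at 280 CPM in the PBS library and 1703 CPM in the infected library, a 6.09-fold difference [5.94, 6.24]. Vtcn1, an inhibitory ligand for T cells, was 12.9-fold higher [9.80, 17.2], the connexin gene Gjb1 14.2-fold higher [10.6, 19.5] and the D-lactate dehydrogenase gene Ldhd 7.76-fold higher [6.97, 8.64]. The pan-leukocyte gene Ptprc stood at 5.91 CPM in the PBS library and 30.4 CPM in the infected library, and Coro1a at 15.7 and 58.1 CPM.

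Peg10 is imprinted together with its neighbour Sgce. Peg10 was 42.8-fold higher in the infected library, whereas Sgce stood at 30.5 and 34.2 CPM, a 1.12-fold difference [1.02, 1.23]. Eef1a1, Eef2, Eef1b2 and Rack1 were 1.54-, 1.63-, 1.51- and 1.39-fold lower, none past 2-fold. Kdm5d, a Y-linked gene and the 1 measured member of the sex-linked list, was, in these libraries from female mice, listed at 13.2 and 11.9 CPM. The Y-linked Ddx3y and Uty were listed at 0 in both, and Xist, also in that list, was not measured. Kdm5c, the X-linked homologue of Kdm5d, stood at 172 and 168 CPM.

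The uroplakins and Krt20 were lower beside higher basal keratins. The median log2 ratio of the 5 uroplakins and Krt20 was -1.43, from -1.64 to -0.90. Neutrophil genes were higher, but the 15 measured held only 139 CPM together in the infected library. The superficial and the basal and intermediate lists held 12616 and 17467 CPM there. Such sums of markers do not give the share of RNA from each cell type. A general dilution of urothelial RNA by other cells would lower basal genes alike. The lower quartile of the basal and intermediate list was 0.46, so dilution alone does not give the pattern. The pattern was drawn up with the basal genes already seen to be higher, so they give no independent test. A rise in basal genes could hide a dilution, so a part played by dilution in the lower uroplakins stays open. A loss of superficial cells, as by exfoliation or by uneven dissection, may account for the lower values. It would lower the 6 genes by one factor only if all were confined to superficial cells, which was not tested. Their spread of 0.74 therefore neither shows nor excludes such a loss. These 6 genes were picked, after their values were seen, from the 13 measured in the superficial list. Of the rest, Upk3bl and Krt18 had log2 ratios of -0.44 and -0.42, and Krt8, Gsdma, Trpv4, Krt19 and Prss27 were higher, at 0.11, 0.31, 0.31, 0.78 and 1.72. A loss of cells alone does not raise those 5, but Krt8 and Krt19 also occur in deeper layers. Loss of superficial cells and lower expression per cell therefore cannot be told apart for the 6 genes.

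Smooth muscle genes were lower in a sample described as dissected urothelium. The 11 contractile genes had a median of -1.23, with quartiles of -1.37 and -1.04. Smtn was the member that was higher, at 1.13-fold [1.06, 1.20]. Dilution of all stromal cells would lower endothelial genes too, and the lower quartile of the endothelial list was 0.046, above the upper quartile of the contractile genes. This argues against such dilution as the whole cause only if infection did not itself raise endothelial genes, which was not tested. Of the 14 endothelial genes, 4 had lower values. Fibroblast genes were lower too, with a median of -0.35, so a smaller dilution of part of the stroma stays open. The pattern was first seen in the contractile genes, so they give no test of less muscle layer carried along. With 1 library per group, a difference in dissection and an effect of infection on muscle cannot be told apart.

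Ezh2 was higher beside the cell cycle genes. Counting error alone is argued against by the lower bound of its fold, 1.91. The log2 ratio of Ezh2 was 1.05, below the median of 2.20 of the 40 cell cycle genes, which ranged from 1.19 to 2.69, and that of Ezh1 was -0.34. A larger share of cycling cells in the infected sample is a candidate explanation. The comparison was chosen after these values were seen, and any modestly higher gene would meet it, so it gives no support. An effect of infection on Ezh2 itself was not separated from a larger share of cycling cells. With 1 library per group the difference between animals stays open.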
